A study of Mus musculus with 6 samples.

How the data were processed

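Total RNA was taken from hepatocytes of wild-type C57BL/6 mice aged 3 weeks, right after the living cells had been stained with a Hoechst DNA dye and sorted by flow cytometry into diploid and tetraploid fractions, per the labels' protocols. Biotin-labelled cRNA was hybridised to 6 Affymetrix arrays, 3 per fraction. The sample titles gave each array its fraction and its replicate number.

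The deposited table holds one intensity per probe set and array on a linear scale. The submitters' processing notes name RMA, a method that corrects background, equalises the distribution of the arrays and summarises the probes of a probe set. Its version, software and any further filter are not given in the sources used here. The linear scale was read from the values themselves, whose array medians lay between 86.4 and 89.2. Because the arrays were brought to nearly the same distribution by the authors, a difference in the total amount of RNA per cell between the fractions was removed from these intensities. Every difference below is relative to the other transcripts of the same array. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.095.

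Intensities were converted to log2. Of 22690 probe sets, 64 controls were left out. The platform annotation gave 1 gene symbol to 20380 probe sets, several symbols to 691 and none to 1555. Symbols were compared with the RefSeq gene table of assembly GRCm38.p6 through Entrez identifiers, which matched for 20364 probe sets and changed 0 symbols. Probe sets with several symbols or none were not assigned to a gene. For each of 12393 genes, the probe set with the highest mean over the 6 arrays was used. The 25% of genes with the lowest mean, below a log2 intensity of 5.06, were then left out, which removed 3098 genes and left 9295. A value from a dim gene lies close to the array background, so its differences are compressed. A probe set of the kind that can match several transcripts stood for 12 of the 63 genes whose differences are given. Of these 63 genes, 34 had over 1 probe set, and for 23 of them another probe set gave a difference over 1.5 times smaller or of the opposite sign, the latter for Afp, Ccnd1, Cdt1, Chek1, Clec4g, Hsd17b6, Lats2 and Ttr.

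The fractions were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with ploidy as the single factor and Benjamini-Hochberg adjusted p-values at a threshold of 0.05. Log2 differences are tetraploid minus diploid, with the standard error from the limma fit. Group levels are means of log2 intensity with the SD over 3 arrays. The test, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined, apart from the choices named as made later. A total of 47 gene lists, 37 of pathways or gene functions and 10 of cell type markers, were written from general knowledge of liver and cell cycle biology. They were tested as 1 family with limma's camera at a preset correlation between genes of 0.01, which compares the members of a list with all other genes. Camera with an estimated correlation and limma's fry, which asks whether the members move one way on balance, were run as alternatives. Within each list, p-values were also adjusted over the list alone. The score of a list on an array is the mean over its tested members of the log2 value minus the mean of that gene over the 6 arrays. Its 95% interval uses the spread over arrays. Exact two-sided permutation tests of single scores used all 10 splits of the 6 arrays and cannot give a p below 0.1.

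The genes named are the 5 with the smallest unadjusted p in each direction, members of each described list among the 4 with the smallest p, and a set of reference genes for hepatocyte identity, zonation, Hippo and p53 signalling and the cell cycle. Genes from outside this rule are marked as chosen after their values were seen. Of the reference genes, Ccnb1 and E2f7 had no probe set with that symbol alone, and Ccn2, Ankrd1 and Ptprc were among the dim genes.

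Both procedures were tested on simulated data with the 9295 genes of this comparison, in 20 runs. For the gene test, 200 genes were changed. For the list tests, separate values were simulated in which only the list of G1/S and DNA replication genes was shifted. Its members were lowered by a fixed log2 amount on the tetraploid arrays. The gene test recovered 84.1% of genes changed 1.5-fold, 98.1% of genes changed 2-fold and 99.8% of genes changed 4-fold, and 5.53% of its calls were false. Camera, camera with an estimated correlation and fry each called the shifted list in 20 of 20 runs. The simulated noise was independent between genes and used variances that limma had already drawn towards a common value. On the real arrays the correlation estimated between members of a list ran from -0.21 to 0.86 over the lists. The simulated recovery and list calls therefore need not hold for the real arrays. Alternatives covered the filter on dim genes, the replicate number as a block, a trend in the variance, array weights, other ways of joining probe sets, rescaling of the arrays, a looser threshold, other list tests and leaving out each array in turn. No processed file was left unused.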

Results

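Gene expression was measured in primary mouse hepatocytes sorted by DNA content. Diploid hepatocytes carry the usual chromosome complement of body cells, and tetraploid hepatocytes, which accumulate in the mouse liver as it matures, carry a duplicated complement in a single nucleus or spread over a pair of nuclei. Each fraction was represented by 3 arrays. The fractions were set by DNA content, so the tetraploid fraction may also hold diploid cells in G2 or mitosis. The labels call the replicates biological, but do not say whether they came from separate animals, so the p-values measure the spread between these samples, which may be technical in part. The arrays resembled each other closely, with a Pearson correlation across probe sets between 0.992 and 0.997 for the 15 pairs of arrays. The comparison of the fractions asks which transcripts differ between diploid and tetraploid hepatocytes of the same developmental age.

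Genes of DNA replication were lower as a set in tetraploid than in diploid hepatocytes by limma's camera (adjusted p = 3.69e-41), a call lost at an adjusted p = 0.468 with an estimated correlation. All 37 tested members of the list of G1/S and DNA replication genes had a lower mean in the tetraploid fraction, and the median log2 difference was -0.66. Uhrf1, which recruits the maintenance DNA methyltransferase to newly copied DNA, had a log2 intensity of 8.54 ± 0.34 in diploid and 6.99 ± 0.22 in tetraploid cells (SD, n = 3), a log2 difference of -1.55 ± 0.18 (SE), and a second, dimmer probe set differed by -0.62. Mcm5 and Mcm7, subunits of the replicative helicase, differed by -1.41 ± 0.22 and -1.02 ± 0.16. Cdc45, which joins that helicase at the replication fork, differed by -0.64 ± 0.09, and E2f8, a repressor in the E2F family that acts in the polyploidisation of hepatocytes, by -0.68 ± 0.20.

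Of these 37 genes, 33 were lower when adjusted over the list alone and 0 when adjusted over all genes tested with limma. In 32 of them the 3 tetraploid values did not overlap the 3 diploid values, where chance gives 10% of genes. The correlation estimated between genes of the list was 0.48, and fry gave an adjusted p = 0.206. The score of the list differed by -0.69 ± 0.14 (SE), with a 95% interval from -1.09 to -0.29. The exact permutation test of the score gave p = 0.1, the smallest p that 3 arrays against 3 allow. The list shared 0 tested members with any other list. Of the 68 probe sets that measured its genes, 66 were lower in the tetraploid fraction.

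**Figure D1:**
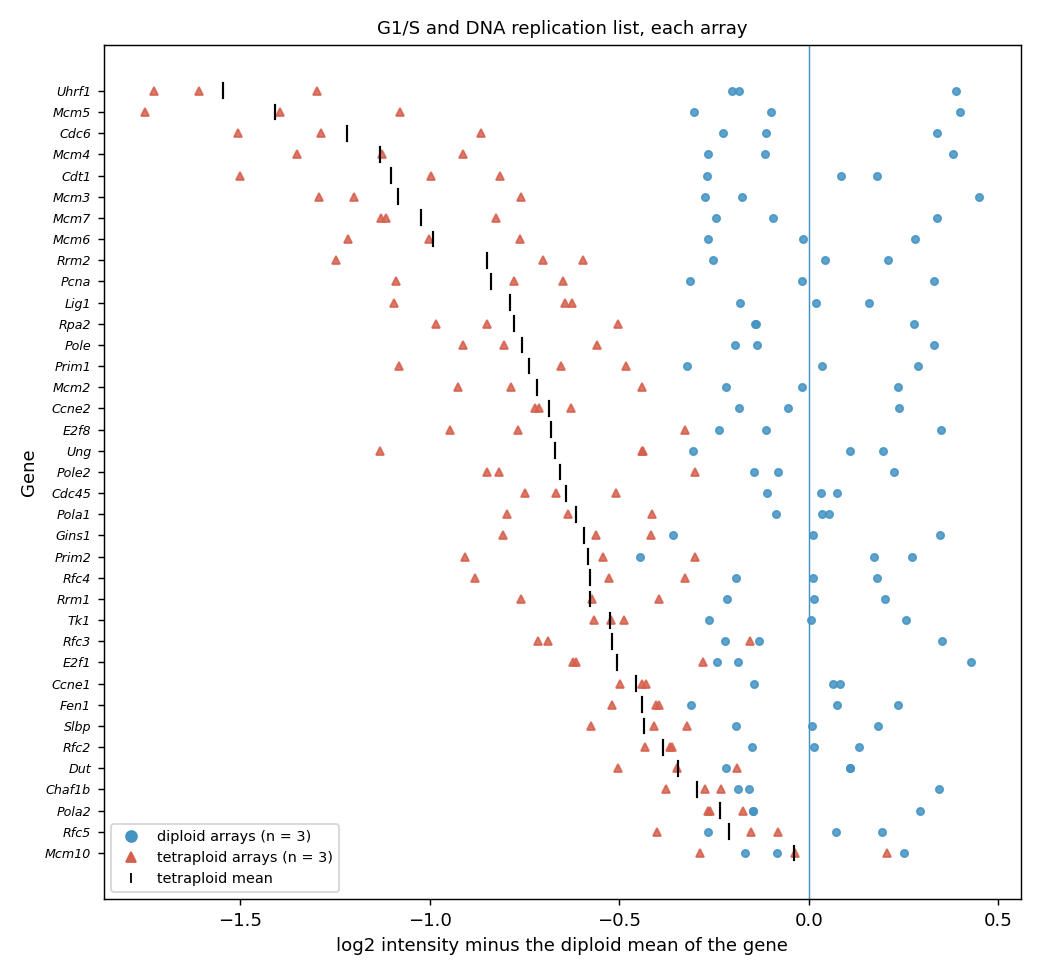
Log2 intensity of each of the 37 tested G1/S and DNA replication genes on each array, minus the diploid mean of the gene (horizontal axis, log2 units), with 3 diploid arrays as circles, 3 tetraploid arrays as triangles and the tetraploid mean as a vertical tick. The tetraploid mean lies left of 0 for all 37 genes, and the fractions do not overlap in 32.

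The single genes with the smallest p-values did not pass the threshold. The lowest unadjusted p-values among genes with lower levels in tetraploid cells belonged to Uhrf1, Topbp1, Hells, Cdc45 and Dtl. Topbp1, which activates the ATR checkpoint kinase, differed by -0.65 ± 0.08. Hells, a chromatin remodeller needed for DNA methylation, differed by -1.27 ± 0.17, and Dtl, the substrate receptor of a ubiquitin ligase that degrades Cdt1 in S phase, by -1.10 ± 0.16 (SE, n = 3 per fraction). In the other direction the smallest p-values belonged to Cyp3a16, Gda, Habp2, Pcdh1 and Chmp4c. Cyp3a16, a cytochrome P450 of the young mouse liver, differed by 1.28 ± 0.17, a 2.43-fold higher level. Its close paralogs in the Cyp3a family can bind the same probes, so the value is uncertain as to the gene, and Cyp3a44 differed by 0.30 ± 0.09. Gda, a guanine deaminase, differed by 0.50 ± 0.09, Habp2, a serine protease of plasma, by 0.36 ± 0.07, Pcdh1, a cell adhesion protein, by 0.36 ± 0.07, and Chmp4c, a subunit of the abscission machinery, by 0.41 ± 0.09. Second, dimmer probe sets differed by -0.05 for Dtl, 0.09 for Habp2 and 0.09 for Chmp4c. That for Habp2 had a mean log2 intensity of 7.74, well above the cutoff of 5.06 for dim genes. The probe sets used for Chmp4c, at 4.93 in diploid cells, and Dtl, at 4.92 in tetraploid cells, were themselves near that cutoff.

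By limma without a replicate block, 0 of 9295 genes passed an adjusted p of 0.05, 0 of them higher and 0 lower. The smallest adjusted p was 0.211, shared by 18 genes. At an unadjusted p under 0.05 there were 574 genes, 216 higher and 358 lower in the tetraploid fraction, where 465 are expected by chance. Without diploid replicate 1 there were 378. A total of 12 genes differed by over 2-fold, of which 11 were lower, and 7 of those 11 were on the DNA replication list. For 93.7% of genes the log2 difference lay within 0.25, and 1143 genes (12.3%) had fractions that did not overlap, against 10% by chance. Over all 22626 probe sets without controls, 0 passed and 1561 had an unadjusted p under 0.05. Leaving out tetraploid replicate 1 gave 1 gene past the threshold, Hells.

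Genes of DNA damage repair were lower in tetraploid cells as a set by camera (adjusted p = 2.35e-06), with an adjusted p = 0.604 with an estimated correlation. Of 27 tested members, 21 were lower and 6 higher on average. Adjusted over the list alone, 7 were lower and 0 higher, and adjusted over all genes 0 passed. The differences were -0.63 ± 0.10 for Rad54l, -0.70 ± 0.11 for the exonuclease Exo1 and -1.10 ± 0.18 for the checkpoint kinase Chek1 (SE, n = 3 per fraction). Of the 4 probe sets for Chek1, the brighter pair was lower and the dim pair differed by 0.05 and 0.09. Other, dimmer probe sets differed by -0.29 and -0.22 for Rad54l and by -0.22 for Exo1. The one for Exo1, at a mean log2 intensity of 5.10, was nearly as bright as the one used, at 5.21. The list's median was -0.11 and its mean -0.24, and the median was -0.22 without diploid replicate 2 and -0.06 with the stricter filter on dim genes.

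Genes of G2/M and mitosis were not called as a set on all 6 arrays. Of 44 tested members, 27 were lower and 17 higher on average, and 2 were lower when adjusted over the list alone, with 0 adjusted over all genes. These were Ncaph and Ncapg2, subunits of the condensin complexes, at -0.52 ± 0.11 and -0.86 ± 0.18. The proliferation marker Mki67 differed by -0.12 ± 0.17 and Top2a, the topoisomerase of mitotic chromosomes, by -0.53 ± 0.27 (SE, n = 3 per fraction), with overlapping fractions in both. The score of the list differed by -0.05 ± 0.21 (SE), with a 95% interval from -0.64 to 0.54, and camera gave an adjusted p = 0.515, and 0.937 with an estimated correlation. Single arrays decided this list, which was lower past the threshold without diploid replicate 2 (adjusted p = 0.000851) or tetraploid replicate 2 (0.000748), and leaned higher without passing when either replicate 3 was left out (0.239 and 0.107). The arrays of each fraction were spread widely on this score. Diploid replicates 1 to 3 were at 0.05, -0.24 and 0.27, and tetraploid replicates 1 to 3 at 0.006, 0.22 and -0.30. Each fraction held a high and a low array, so leaving out 1 of them unbalanced the comparison.

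Cytokinesis and abscission genes were divided evenly, with 13 of 26 tested members higher, 13 lower and 0 past the threshold adjusted over the list alone or over all genes. Anln, which organises the contractile ring, differed by -0.28 ± 0.22, and Spast, a microtubule-severing enzyme of abscission, by 0.20 ± 0.07 (SE, n = 3 per fraction). The list score differed by 0.0007 ± 0.069 (SE), and camera gave an adjusted p = 0.601. Of 16 centrosome and centriole genes, 14 were lower on average and 0 passed adjusted over the list alone, and the list had an adjusted p = 0.105, but passed without diploid replicate 1 (0.0318) or with array weights (0.0498).

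Genes of hepatocytes around the central vein were higher, and genes of hepatocytes around the portal tract lower, in the tetraploid fraction by camera. The pericentral list had an adjusted p = 4.44e-07, and an adjusted p = 0.468 with an estimated correlation. The periportal list had an adjusted p = 7.04e-06, and an adjusted p = 0.604 with an estimated correlation. Of 36 tested pericentral genes, 31 were higher on average, with a median log2 difference of 0.18, and 0.11 when every probe set was counted. Adjusted over the list alone or over all genes, 0 members passed. The pericentral members with the smallest p-values were Oat, the ornithine aminotransferase, at 0.26 ± 0.08, the vasopressin receptor Avpr1a at 0.25 ± 0.08, Gulo, which completes vitamin C synthesis, at 0.29 ± 0.09, and the phosphatase Lhpp at 0.27 ± 0.09 (SE, n = 3 per fraction). Glul, the glutamine synthetase of the innermost pericentral cells, differed by -0.11 ± 0.11, and the cytochrome P450 gene Cyp2e1 by 0.11 ± 0.07.

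Of 34 tested periportal genes, 27 were lower on average, with a median of -0.08 and a mean of -0.14, and the median was -0.13 without tetraploid replicate 3. The 95% interval of the score difference ran from -0.29 to 0.004. Adjusted over the list alone, 7 were lower, and adjusted over all genes 0 passed. Hsd17b6, a steroid dehydrogenase, differed by -0.48 ± 0.09, the mitochondrial aldehyde dehydrogenase Aldh1b1 by -0.46 ± 0.10, Pigr, which carries immunoglobulin A into bile, by -0.46 ± 0.11, and the apolipoprotein Apoa4 by -0.30 ± 0.07 (SE, n = 3 per fraction). A second, dim probe set for Hsd17b6 differed by 0.20. Hal, which starts histidine breakdown, and Cyp2f2, a periportal cytochrome P450, differed by -0.39 ± 0.10 and -0.32 ± 0.08.

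The scores of the pericentral and periportal lists differed by 0.15 ± 0.03 and -0.14 ± 0.05 (SE). The pericentral score minus the periportal score lay between 0.11 and 0.19 on the tetraploid arrays and between -0.26 and -0.07 on the diploid arrays, with p = 0.1 in the exact permutation test, the smallest possible. Other lists held part of these genes, and restricted to the 12 pericentral and 14 periportal genes found on no other list, a restriction chosen after seeing the data, camera gave an adjusted p = 4.82e-06 and 9.49e-05, and an adjusted p = 0.685 for both with an estimated correlation.

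**Figure D2:**
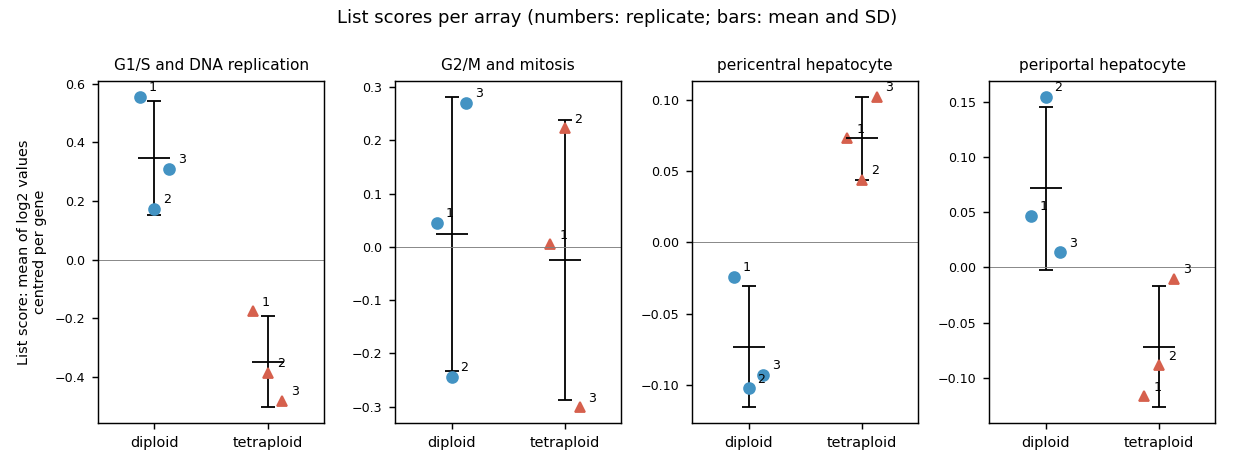
List score of each array, as the mean log2 value of the list's genes after centring each gene (vertical axis, log2 units), for 4 gene lists, each panel on its own scale, with diploid arrays as circles, tetraploid arrays as triangles, the replicate number beside each point, and bars for the mean and SD of 3 arrays. The fractions do not overlap for the DNA replication list and overlap for the G2/M list.

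Hippo signalling, which limits organ size, was not called as a set. Of 23 tested pathway components, 13 were higher and 10 lower on average, and of 16 tested targets of YAP and TAZ, the co-activators that Hippo signalling restrains, 9 were higher and 7 lower. In both lists 0 genes passed adjusted over the list alone or over all genes. The kinase Lats2 differed by 0.17 ± 0.20, the upstream kinase Stk4 by 0.36 ± 0.14, and among the targets Dlc1 differed by 0.45 ± 0.25 and the matrix protein gene Ccn1 by -0.14 ± 0.26 (SE, n = 3 per fraction). The 6 probe sets for Lats2 went in both directions. The 95% interval of the score difference ran from -0.09 to 0.16 for the components and from -0.09 to 0.20 for the targets, and camera gave an adjusted p = 0.601 and 0.515. Ccn2 and Ankrd1, common readouts of YAP activity, were at log2 intensities of 4.59 ± 0.10 and 4.22 ± 0.14 in diploid cells (SD, n = 3), among the dim genes left out.

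Of 26 tested p53 target genes, 15 were higher and 11 lower on average. The RNA-binding protein gene Zmat3, at 0.35 ± 0.08, and the cyclin Ccng1, at 0.47 ± 0.11, were higher when adjusted over the list alone, and 0 members passed adjusted over all genes. At an unadjusted limma p under 0.05, 2 members were higher and 2, Ddb2 and Psrc1, were lower. The fractions did not overlap for 3 higher and 3 lower members. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, differed by 0.08 ± 0.41 and was spread widely within both fractions, at 6.95 ± 0.71 in diploid and 7.03 ± 0.65 in tetraploid cells (SD, n = 3). The ubiquitin ligase Mdm2 differed by 0.13 ± 0.14 (SE), and a second, dimmer probe set by 0.34. Camera gave an adjusted p = 0.126 for the list, and 0.0250 without tetraploid replicate 1. Among 17 genes of senescence and cyclin-dependent kinase inhibition, Rbl1, a pocket protein of the retinoblastoma family, was lower when adjusted over the list alone, at -0.61 ± 0.12, and the list had an adjusted p = 0.801. A second, dim probe set for Rbl1 differed by -0.15. The cyclin Ccnd1 differed by -0.05 ± 0.14.

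Lists of energy metabolism had medians close to 0. Of 45 tested genes of oxidative phosphorylation, 40 were lower on average, with a median of -0.07, and Cyc1, cytochrome c1 of the respiratory chain, differed by -0.17 ± 0.07 (SE, n = 3 per fraction). Of 34 genes of fatty acid oxidation and PPARa targets, 25 were higher, with a median of 0.05, among them the ketone body enzyme Bdh1 at 0.24 ± 0.07 and the acyl-CoA thioesterase Acot4 at 0.33 ± 0.10. In both lists 0 genes passed adjusted over the list alone or over all genes. Camera gave an adjusted p = 0.00164 for oxidative phosphorylation and 0.0293 for fatty acid oxidation, against an adjusted p = 0.689 and an adjusted p = 0.663 with an estimated correlation. Oxidative phosphorylation lost its call without tetraploid replicate 3 (adjusted p = 0.0686), and its median was -0.04 without diploid replicate 1. Fatty acid oxidation lost its call without tetraploid replicate 3 (0.0828), tetraploid replicate 2 (0.322, median 0.02), diploid replicate 1 (0.0672) or diploid replicate 2 (0.0877, median 0.03).

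Markers of hepatocytes were not called as a set, with 11 of 20 tested genes higher, 9 lower and a median of 0.0005 (camera adjusted p = 0.743). Alb and Ttr, the albumin and transthyretin genes, differed by 0.01 ± 0.06 and 0.04 ± 0.07 (SE, n = 3 per fraction). The Alb probe set was the brightest on all 6 arrays, where equalising the arrays fixes its value, so a difference in Alb could not be measured. Ttr, at 15.42 ± 0.04 in diploid and 15.46 ± 0.02 in tetraploid cells (SD, n = 3), lay close to this upper end too, where a difference may be compressed. Afp, the fetal albumin homologue, differed by 0.29 ± 0.12, with fractions that did not overlap, and by 0.16 without diploid replicate 1. Its other, dimmer probe sets differed by 0.20, 0.18, 0.06 and -0.08.

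Markers of liver endothelial cells, a cell type the sort could still hold, were higher in the tetraploid fraction as a set by camera (adjusted p = 0.0245), with an adjusted p = 0.700 with an estimated correlation. Of 19 tested genes, 13 were higher and 6 lower, with a median of 0.13, and 1 passed adjusted over the list alone, the water channel gene Aqp1 at 0.47 ± 0.10, while 0 passed adjusted over all genes. The scavenger receptor Mrc1 differed by 0.35 ± 0.13, the Fc receptor Fcgr2b by 0.34 ± 0.13, the lectin Clec4g by 0.34 ± 0.14 and the scavenger receptor Stab2 by -0.24 ± 0.21 (SE, n = 3 per fraction). A second, dim probe set for Clec4g differed by -0.05, and the other 3 for Fcgr2b by 0.02, 0.27 and 0.13. The call was lost without diploid replicate 3 (adjusted p = 0.363, median 0.06) or tetraploid replicate 3 (adjusted p = 0.274, median 0.07). It was also lost with the stricter filter on dim genes, with every probe set and with ranks. Restricted to the 18 genes found on no other list, which drops Aqp1, camera gave an adjusted p = 0.106. This restriction was chosen after seeing the data. Of 12 markers of Kupffer cells and macrophages, 4 were higher and 8 lower, with Clec4f at -0.03 ± 0.07 and an adjusted p = 0.601 for the list. The score of 7 markers of T and NK cells differed by -0.08 (95% interval -0.11 to -0.05) and that of 5 platelet and megakaryocyte markers by -0.10 (-0.19 to -0.01), and neither list was called by camera (adjusted p = 0.438 and 0.216), although T and NK cell markers passed with no filter on dim genes (0.0316).

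In all, 7 of the 47 lists passed camera at the preset correlation, 4 of them lower and 3 higher in the tetraploid fraction, and 0 passed with an estimated correlation or with fry's test of a shift one way. In fry's test of change in either direction 4 lists passed, those of repair, periportal, DNA replication and xenobiotic metabolism genes, each at an adjusted p = 0.0479. The mean log2 difference of the 40 lists that did not pass lay between -0.16 and 0.10. Leaving out diploid replicate 1, whose intensity distribution lay farthest from the others, gave 12 lists past the threshold in place of 7.

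**Figure D3:**
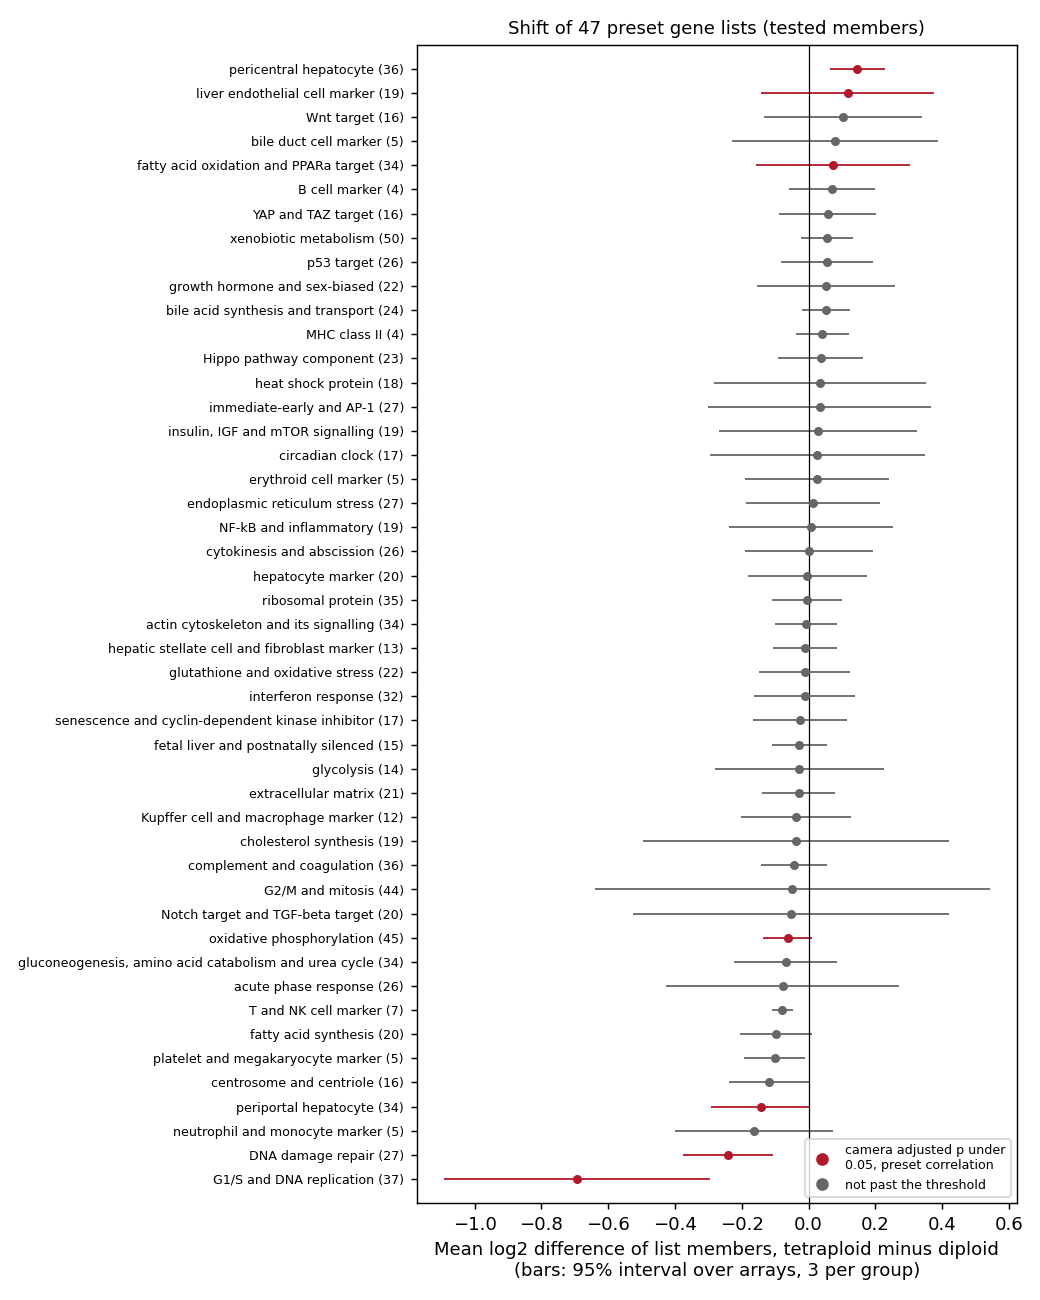
Mean log2 difference of the tested members of each of the 47 lists, tetraploid minus diploid (horizontal axis), with bars for the 95% interval over 3 arrays per fraction, red for the 7 lists past the threshold in camera at the preset correlation. The DNA replication list lies farthest from 0, at -0.69.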

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

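Alternatives were run for the counts of genes and lists, the lists described and the genes whose differences are given. The lists that were not called, and the number of replication genes that passed within their list, were added to these after seeing the data. Permutation tests, artifact tests and list scores were not rerun. The median of the DNA replication list stayed lower under each alternative, from -0.73 without diploid replicate 2 to -0.56 without tetraploid replicate 3, and with 1 array left out its camera adjusted p ran from 5.92e-43 to 1.01e-29. Genes lower within this list numbered 27 to 35 with 1 array left out, and 53 when every probe set was counted, since several probe sets then stand for a gene. Genes past the threshold numbered 0 to 1 with 1 array left out (0 higher, 0 to 1 lower), and 0 at a looser adjusted p of 0.1. Genes with an unadjusted p under 0.05 numbered 378 to 639 with 1 array left out, 369 with the stricter filter on dim genes and 1129 when every probe set was counted.

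The replicate numbers are shared by the fractions, but same-numbered arrays did not deviate together throughout, with correlations of deviations from the fraction means of 0.44, -0.15 and -0.16 for replicates 1, 2 and 3. Diploid replicate 2 correlated best with tetraploid replicate 3 (0.24) and diploid replicate 3 with tetraploid replicate 2 (0.56), which is a hint from the data, not the design. With the number as a replicate block, 9 genes passed, 9 of them lower, so the count of genes depended on this block. They were Uhrf1, Mcm5, Cdc6, Mcm3 and Mcm7 of the replication list, and Chek1, Dtl, Timeless and Fignl1, with Cdc6, Mcm3, Timeless and Fignl1 named after their values were seen, and with adjusted p from 0.0194 to 0.0481. The block also gave 8 lists past the threshold and 32 replication genes lower within their list.

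Lists past the threshold numbered 12 with array weights, 0 with an estimated correlation, 0 with fry, and 5 to 12 with 1 array left out. With an estimated correlation the adjusted p was 0.468 for DNA replication, 0.604 for repair, 0.689 for oxidative phosphorylation, 0.663 for fatty acid oxidation, 0.468 for pericentral, 0.604 for periportal and 0.700 for endothelial genes. With fry the values were, in that order, 0.206, 0.206, 0.372, 0.526, 0.206, 0.215 and 0.670. Fatty acid oxidation had 0.0668 with the stricter filter on dim genes and 0.00103 to 0.322 with 1 array left out. Endothelial markers had 0.626 with the stricter filter, 0.118 with every probe set, 0.0743 with ranks and 0.000762 to 0.363 with 1 array left out. Oxidative phosphorylation had 0.000200 to 0.0686 with 1 array left out. The pericentral median was 0.14 with array weights, 0.13 with the mean of probe sets, 0.11 with every probe set and 0.12 to 0.21 with 1 array left out.

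Lists that were not called could pass under another setting. G2/M genes had 0.000748 to 0.670 with 1 array left out, lower where they passed and higher without passing when either replicate 3 was left out. Centrosome genes had 0.0498 with array weights and 0.0318 to 0.468 with 1 array left out, and p53 targets 0.0250 to 0.355. Xenobiotic metabolism had 0.0188 with no filter, 0.0260 with a variance trend, 0.0498 with array weights, 0.0229 after quantile normalization and 0.0415 to 0.270 with 1 array left out. Gluconeogenesis, amino acid catabolism and urea cycle genes had 0.00789 with the stricter filter, 0.0109 with a variance trend, 0.0335 with array weights and 0.0259 to 0.412 with 1 array left out. Fatty acid synthesis had 0.0498 to 0.387, and T and NK cell markers 0.0316 with no filter. Other lists leaned the other way in part, never past the threshold. Ribosomal protein genes did so at 0.948 with the stricter filter, 0.971 with the mean of probe sets, 0.749 with every probe set and 0.986 with fry, and cytokinesis genes at 0.992 with every probe set. The stricter filter left fewer than 3 Kupffer cell, T and NK cell, platelet and neutrophil genes, too few to test. With 1 array left out the values were 0.281 to 0.89998 for ribosomal protein, 0.308 to 0.960 for cytokinesis, 0.363 to 0.938 for Hippo component, 0.404 to 0.938 for senescence, 0.404 to 0.938 for hepatocyte and 0.308 to 0.938 for Kupffer cell genes.

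Leaving out 1 array moved 17 of the 63 genes whose differences are given by over 1.5 times, 0 of them among those that passed within a list. Some genes near 0 changed sign. Cdkn1a was -0.00697 with array weights. With 1 array left out, the lowest and highest values were -0.30 and 0.48 for Cdkn1a, -0.00324 and 0.0190 for Alb, -0.36 and 0.0756 for Ccn1, -0.0714 and 0.32 for Lats2, -0.0257 and 0.24 for Mdm2, -0.17 and 0.0704 for Ccnd1, and -0.28 and 0.0355 for Mki67. Cdkn1a was high on diploid replicate 3, at 7.77, and on tetraploid replicate 2, at 7.78. Its extremes of 0.48 and -0.30 came from leaving out these arrays, in that order, which removed a high value from 1 fraction only. The cause of the other changes was not tested. Dim genes lie near the array background, where differences are compressed.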

Other observations

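The tests of other cell types, of a single array, of all proliferation genes and of the hepatocyte share were chosen after the results they bear on had been seen, as were the genes named next. The helicase loaded at replication origins was lower in the tetraploid fraction in each of its 6 subunits, MCM2 to MCM7, with non-overlapping fractions for all 6. Besides Mcm5 and Mcm7, the log2 differences were -0.72 ± 0.16 for Mcm2, -1.08 ± 0.21 for Mcm3, -1.13 ± 0.18 for Mcm4 and -0.99 ± 0.16 for Mcm6 (SE, n = 3 per fraction). Cdc6 and Cdt1, which load this helicase, differed by -1.22 ± 0.20 and -1.10 ± 0.19, with another, dim probe set for Cdt1 at 0.07. None of these genes passed limma over all genes tested in the comparison without a replicate block.

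Further lists had shifts that did not pass camera on all 6 arrays with the main settings. Of 50 tested genes of xenobiotic metabolism, 32 were higher and 18 lower, and 1, Cyp3a16, was higher when adjusted over the list alone (list adjusted p = 0.0671). Of 34 genes of gluconeogenesis, amino acid catabolism and the urea cycle, 27 were lower, 10 of the tested members being shared with the periportal list (adjusted p = 0.0671). Of 20 genes of fatty acid synthesis, 16 were lower (adjusted p = 0.105), and all 5 tested markers of neutrophils and monocytes were lower, with a median of -0.12 (adjusted p = 0.105). Of 35 ribosomal protein genes, 19 were higher and 16 lower, with a median of 0.002 (adjusted p = 0.853).

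The lower DNA replication genes in tetraploid cells were weighed against technical explanations. A single array would have to carry the shift, but with 1 array left out the list median nearest to 0 was still -0.56, against -0.66 with all 6. An equal loss of all proliferation genes stays open. The replication score minus the G2/M score differed by -0.64 ± 0.20 (SE), tetraploid minus diploid. The exact permutation test gave p = 0.1, the smallest possible. This difference cannot decide, because diploid cells in G2 or mitosis share the DNA content of the tetraploid gate and may add G2/M transcripts there. The G2/M score also depended on single arrays. Cells of another type among the diploid cells remain open: 15 pooled markers differed by -0.0055 ± 0.044, while the neutrophil and monocyte, platelet and T and NK cell scores differed by -0.16, -0.10 and -0.08 and the endothelial score by 0.12, the other way. Only 2 of the 9 cell types had 3 or more markers at a log2 level of at least 7. Neutrophils and monocytes had 1, platelets 1 and T and NK cells 0, so their scores rest mostly on markers below that level. The brightest pooled markers, Slc40a1 at 11.98 and Cxcl12 at 10.34, need not be specific in sorted hepatocytes. RNA degradation stays open, since the ratio of 3' to 5' control probe sets differed by -0.043 ± 0.036, too little to decide, although the list median was -0.72 after adjusting for this ratio. Ploidy itself and the placing of S-phase, G2 and mitotic cells by a sort on DNA content are confounded by design. A lower share of cells in early S phase in the tetraploid gate is a candidate explanation that was not tested.

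The opposite shifts of the pericentral and periportal lists may reflect where the sorted cells sat in the liver lobule, as a hypothesis. A change in the share of hepatocytes alone would move both lists the same way. The pericentral minus periportal score was instead higher in the tetraploid fraction by 0.29 ± 0.06 (SE), with the lists on opposite sides of 0. These are the same shifts that make up the pattern, so they give no separate test of a change in cell composition. Ploidy itself and a recovery of zones that differs with cell size in the sort remain open and were not tested.

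The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The replication list's median had a size of 0.66 in the real split, reached in 1 of the 10 splits, with 0.48 as the highest of the others. The difference between the zonal medians was 0.25, reached in 1 split, with 0.14 as the highest other. The real split gave 7 lists past the threshold, and 5 of the 10 splits gave as many, up to 12. It gave 574 genes with an unadjusted p under 0.05, and 5 splits gave as many, up to 926. In all 10 splits 0 genes passed the threshold, the highest other being 0.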
